A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

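Gene expression was measured on Affymetrix Yeast Genome 2.0 arrays, 1 sample per array and 1 label per array, in 16 samples from 2 strain labels, 2 RNA fractions and rapamycin or DMSO, 2 replicates per group. Per the labels' protocols, a culture was divided into a portion with and a portion without rapamycin, 4-thiouracil was added after 30 min, and S. pombe cells labelled in the same way were mixed in before RNA extraction. The protocol gives 1 µg/mL rapamycin and the series' design text 5 µM. Labelled RNA was biotinylated and purified on streptavidin beads, per the labels' protocols. The deposited values are intensity values on a linear scale, and the submitters' processing notes name Affymetrix Expression Console 1.4.1; the summary algorithm, background correction and any spike-in scaling are not given in the sources used here. In the deposited intensity columns the mean after trimming 2% at each end is about 500 in those labelled Taf4 and about 100 in those labelled Taf5, so each column was scaled over the probe sets of both species together. Such scaling removes part of any common change in S. cerevisiae RNA. The number of arrays limits the precision.

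Of 10928 probe sets, 7244 were paired with 1 gene symbol, 1 with several and 3683 with none in the annotation used here. Entrez identifiers matched 5498 probe sets of 5449 S. cerevisiae genes to the names of assembly R64, and 1746 probe sets carried S. pombe names. The build behind the array's own annotation is not given, and gene positions are those of R64. No probe set named FPR1, the gene disrupted in these strains, was found under that name, and FPR1 is not analysed here.

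Values were taken as log2 without a pseudocount, and each array was shifted so that its S. pombe median was equal across arrays. The probe set with the highest mean stood for each gene, and the lowest 20% of genes by mean were left out, leaving 4360. Each contrast was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted over the genes of 1 contrast, threshold 0.05), and 10 such contrasts were made. S. pombe probe sets passed through the same filter, leaving 1397, and the same fit. Changes are log2 with the SE from the model. Array medians were compared by exact permutation.

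Every pair of columns was compared before any fit. 6 columns equalled another after division by 5, so the fit over all 16 columns that had been chosen before the data were examined would have counted those scans repeatedly. It was replaced by fits over the 8 columns of 1 strain label (depletion, and newly synthesized against steady-state change) or of 1 fraction label (Taf4 against Taf5), within which no scan recurs. That replacement, the 16-column alternative, the test on S. pombe probe sets and a shift from unchanged S. pombe probe sets were chosen after seeing the data. Of the tests of explanations, those of signal-dependent scaling, compression of bright signals and mRNA turnover were written before their results were seen, and the others after. The other choices, the gene lists and the alternatives were fixed before the data were examined, except that 1 mitochondrial entry that matched no probe set was later dropped from its list.

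32 gene lists were written, of which 29 had tested members. They were tested with camera (correlation preset to 0.01, then estimated) and fry, adjusted over 29 lists. At the preset correlation 15, 13, 14 and 12 lists were called in the Taf4 newly synthesized, Taf4 steady-state, Taf5 newly synthesized and Taf5 steady-state contrasts, and 0 in each with an estimated correlation. The estimates rest on 4 residual degrees of freedom and were high for many lists, for example 0.751 for ribosome biogenesis under the Taf4 labels. A list that did not pass with them is therefore not shown to have moved with the other genes. By fry, 16, 26, 21 and 4 lists passed in these contrasts. Named genes are the 6 largest falls and 6 largest rises per depletion contrast with an adjusted p under 0.05, replicates that do not overlap between groups, a standard name and a probe set specific to 1 gene; the 4 largest each way for other contrasts; the 4 brightest members of each list; and 9 fixed genes of the strains. From these the text names a part, picked after the values were seen. The alternatives were the values as deposited, equal S. cerevisiae medians, a loess curve through the S. pombe probe sets (span 0.7), the brighter S. pombe probe sets, no filter or a 40% filter, the mean over probe sets, an intensity trend, the 8 arrays of 1 fraction, the replicate number as a block, and leaving out each array.

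The fits were tested on simulated data with 200 changed genes. In the Taf4 newly synthesized contrast, run on 4360 genes, 26.9%, 92.5% and 100% of log2 changes of 0.5, 1 and 2 were called, and 0.12% of unchanged genes. For Taf5 newly synthesized RNA 19.4% of changes of 1 and 95.5% of changes of 2 were called, for Taf4 steady-state RNA 88.1% and 100%, and for Taf5 steady-state RNA 17.9% and 97.0%. Noise was drawn separately for each gene and S. pombe probe set. An error of the spike-in shift common to all genes of an array was therefore not simulated, and these rates do not cover it. Figures were drawn with matplotlib 3.10.9.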

Results

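Budding yeast (Saccharomyces cerevisiae) strains were profiled in which Taf4 or Taf5, subunits of the general transcription factor TFIID, can be moved out of the nucleus. In this anchor-away system the protein carries an FRB tag, and rapamycin binds it to a ribosomal protein that carries FKBP12 and leaves the nucleus. Cells had rapamycin or its solvent DMSO for 30 min, and new RNA was then labelled with 5 mM 4-thiouracil for 6 min. The steady-state sample is total RNA, and the newly synthesized sample is the labelled RNA purified from it. Labelled wild-type fission yeast (Schizosaccharomyces pombe) cells, for which no rapamycin is named, were mixed in at 1 part to 3 parts of S. cerevisiae as a spike-in. The labels give 8 groups of 2 samples each, from 2 strains, 2 RNA fractions and 2 treatments. Contrasts of rapamycin against DMSO are called depletion here. No strain without a tagged TFIID subunit was given rapamycin, so effects of the drug itself cannot be told apart from those of depletion. The series asks how many genes depend on TFIID. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

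The deposited table holds 16 columns but 10 distinct arrays. 6 of the 8 columns labelled Taf5 equal a column labelled Taf4 divided by 5, with no probe set differing by more than 0.001 signal units. In each of these pairs the rapamycin label is shared, while the strain and the fraction labels differ. Both Taf4 steady-state columns without rapamycin recur as the Taf5 newly synthesized columns without rapamycin, and both Taf4 newly synthesized columns with rapamycin recur as the Taf5 steady-state columns with rapamycin. Taf4 newly synthesized replicate 1 without rapamycin recurs as Taf5 steady-state replicate 1, and Taf4 steady-state replicate 1 with rapamycin recurs as Taf5 newly synthesized replicate 1. Of the Taf5-labelled columns, only steady-state replicate 2 without rapamycin and newly synthesized replicate 2 with rapamycin equalled no Taf4-labelled column. The deposited labels are therefore named as labels throughout, no sample was reassigned, and apart from an alternative that fits all 16 columns no array entered any fit more than once.

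**Figure D1:**
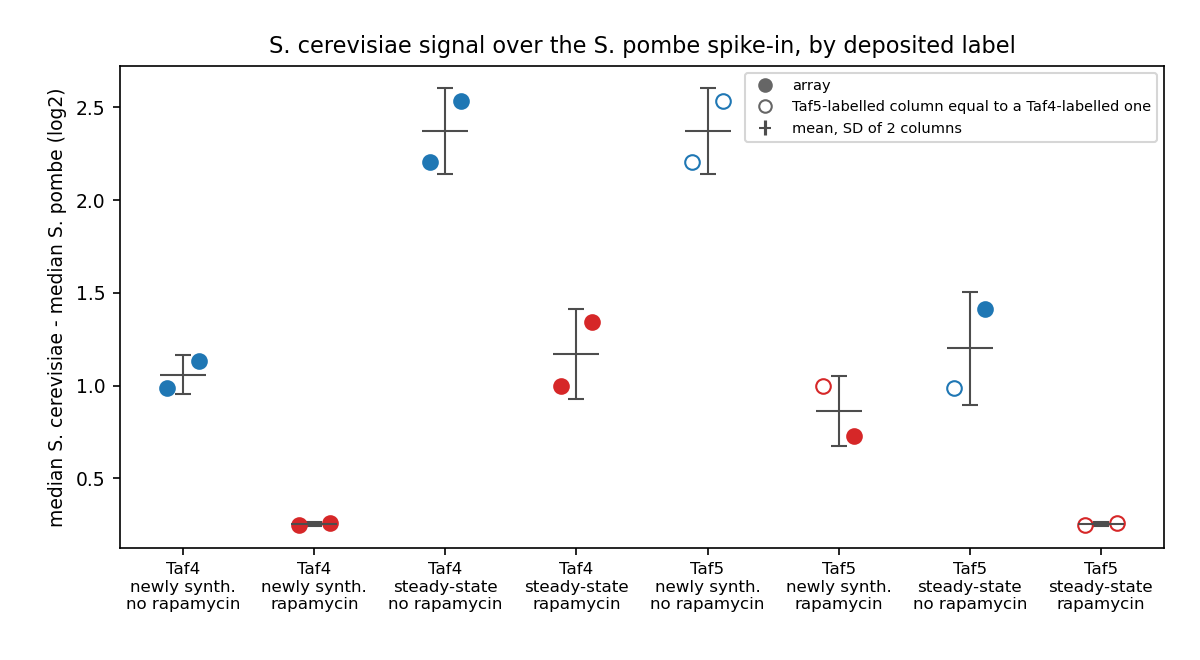
Median log2 signal of S. cerevisiae genes minus that of S. pombe probe sets (y axis) for the 16 columns, by deposited label (x axis); filled points are arrays, blue without and red with rapamycin, open points are Taf5-labelled columns equal to a Taf4-labelled one, and bars are the mean and SD of 2 columns. In the arrays labelled Taf4 newly synthesized the values are 0.99 and 1.13 without rapamycin and 0.25 and 0.26 with it.

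In the arrays labelled Taf4 newly synthesized, most genes were lower with rapamycin. The median over 4360 tested genes was -0.78 on the log2 scale, a 1.72-fold lower level, and 3466 genes were lower and 76 higher at an adjusted p under 0.05 by limma. TAF4 mRNA was 2.54-fold lower (log2 change -1.35, SE 0.22) and TAF5 mRNA 1.57-fold lower (-0.65, SE 0.22), which does not measure the nuclear protein. The largest falls among named genes were in BTN2 (YGR142W, chromosome VII, 772454 to 773686), a protein sorting factor (5.39-fold, SE 0.23 on the log2 scale), and ECM22, a regulator of sterol genes (4.82-fold). Falls of 3.91-fold in SLU7, a splicing factor, 3.86-fold in the hypoxic translation factor gene ANB1, 3.82-fold in the methyltransferase gene EFM3 and 3.77-fold in NTG1, a DNA repair glycosylase, came next. Rises were led by EGO4 (YNR034W-A, chromosome XIV, 692561 to 692857, 5.32-fold), the stress gene DDR2 (4.74-fold), ARG1 of arginine synthesis (4.68-fold), the catalase gene CTT1 (4.07-fold), PGM2, a phosphoglucomutase (3.63-fold), and ARG3 of arginine synthesis (3.49-fold). These 12 genes had adjusted p-values between 5.16e-07 and 1.34e-09, with n = 2 arrays per group.

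Genes of the general stress response moved against the rest in these arrays: 23 of 31 rose and 0 fell, with 23 also adjusted over the list alone. Their median was 0.86 (log2), which is 1.64 above the median of all genes, with HSP12, a membrane stress protein (1.73-fold), and the nicotinamidase gene PNC1 (1.80-fold) among the brightest. The list's shift against all other genes had an adjusted p = 0.0552 with an estimated correlation, so the call made by camera with a preset correlation of 0.01 was lost. All 97 ribosome biogenesis genes fell, also adjusted over the list alone, by a median of -0.98, or -0.20 relative to all genes (adjusted p = 0.887 with an estimated correlation). The pseudouridine synthase gene CBF5 fell 2.47-fold and NOP58, of box C/D particles, 1.79-fold. Of 127 ribosomal protein genes 62 fell and 0 rose (30 adjusted over the list alone), with a median of -0.46, 0.32 above that of all genes (adjusted p = 0.887 with an estimated correlation). RPS31 (-0.37) and RPL30 (-0.43) did not pass, with adjusted p-values of 0.12 and 0.0647, while the anchor gene RPL13A, which carries the FKBP12 tag, fell 1.97-fold.

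Among the transcription machinery, 14 of 15 TFIID genes and 14 of 14 SAGA genes fell (14 and 14 adjusted over the lists alone). Their medians were -0.72 and -0.87, 0.07 above and 0.09 below the median of all genes (adjusted p = 0.962 and 0.887 with an estimated correlation). SPT15, which encodes the TATA-binding protein, fell 1.64-fold, TAF9 1.98-fold, SPT20 1.66-fold and TRA1 1.58-fold. 19 of 20 Mediator genes fell (19 adjusted over the list alone), ROX3 by 2.30-fold, with a list p of 0.887 after adjustment with an estimated correlation. Other lists fell less than the median gene. Of 9 histone genes 1 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.04, and HTA1 (-0.12) and HTB1 (-0.20) did not pass. Of 45 nuclear genes of respiration 5 fell and 5 rose (0 and 0 adjusted over the list alone), among them ACO1, an aconitase, which rose 1.60-fold. Glycolysis and fermentation had 4 of 19 lower and 4 higher (2 and 4 adjusted over the list alone), and TDH3 fell 1.38-fold. Without Taf4 newly synthesized replicate 2 without rapamycin, SPT15, SPT20, TRA1 and TAF5 did not pass (adjusted p = 0.0617, 0.0529, 0.0646 and 0.0656). SPT20 and TRA1 also did not pass without replicate 1 with rapamycin (0.054 and 0.0669), nor TAF5 without replicate 2 with it (0.0797). TDH3 did not pass when any 1 of the 4 arrays was left out (adjusted p = 0.0863 to 0.272), and ACO1 did not pass without replicate 1 without rapamycin or replicate 2 with it (adjusted p = 0.0749 and 0.0638). The adjusted p-values of these last lists with an estimated correlation were 0.252, 0.617 and 0.617.

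The size of the common fall rests on the spike-in. The array medians gave -0.81 (n = 2 per group), for which an exact permutation test, two-sided, gives p = 0.333, the smallest that 2 against 2 arrays allow. With S. cerevisiae medians made equal, 391 genes were lower and 676 higher. Then the medians of ribosomal proteins (0.36), glycolysis (0.50), respiration (0.61) and histones (0.78) lay above 0, as did that of TFIID genes (0.11), with SPT15 (0.11), SPT20 (0.092), TRA1 (0.16) and TAF5 (0.17), while stress genes stayed higher (1.69) and ribosome biogenesis (-0.15), Mediator (-0.15) and SAGA genes (-0.048) lower. On the values as deposited the medians of glycolysis (0.055), respiration (0.16) and histones (0.34) were above 0, and under a loess scaling that of histones (0.098). Of 1397 S. pombe probe sets tested in the same way, 0 differed by limma, and 46 had an unadjusted p under 0.05. A fit on the 8 columns labelled newly synthesized called 2333 S. cerevisiae genes lower and 11 higher by limma, so the count of rises depends on the fit.

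**Figure D2:**
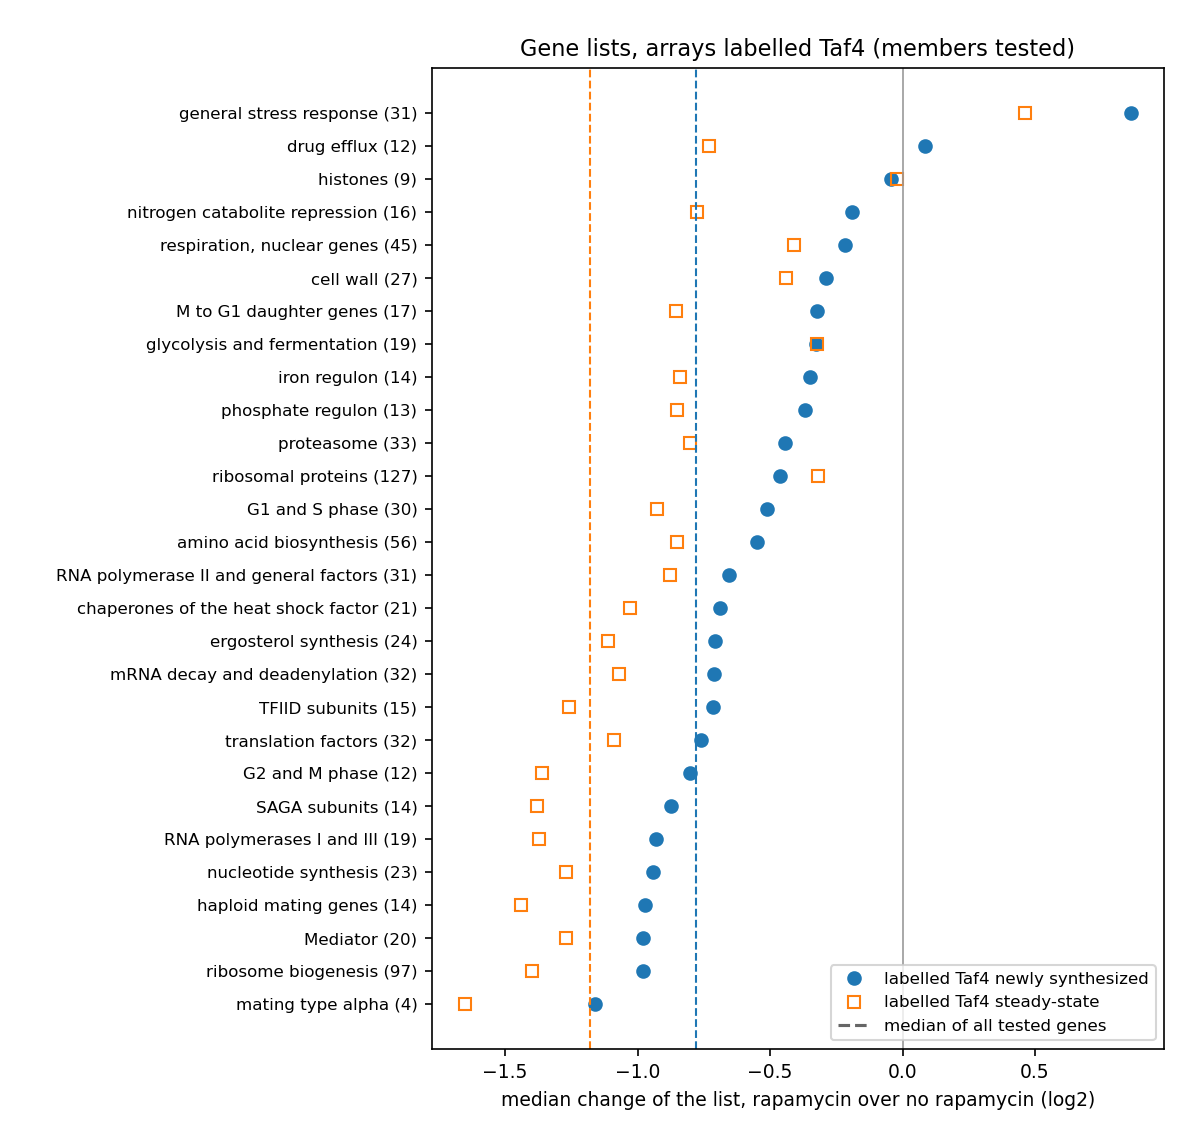
Median log2 change with rapamycin (x axis) of each gene list with at least 4 tested members (y axis, members in brackets) in the arrays labelled Taf4 newly synthesized (circles) and Taf4 steady-state (squares); dashed lines are the medians of all tested genes. General stress response stands above 0 in both (0.86 and 0.46), and ribosome biogenesis lies at -0.98 and -1.40; positions depend on the scaling, since ribosomal proteins, glycolysis, respiration and histones lie above 0 when S. cerevisiae medians are made equal, and steady-state ribosomal proteins lie at -1.64 under a loess scaling.

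In the arrays labelled Taf4 steady-state, 3792 of 4360 genes were lower and 62 higher with rapamycin, by limma at an adjusted p under 0.05. The median gene was 2.27-fold lower (-1.18 on the log2 scale). TAF4 mRNA was 2.83-fold lower (-1.50, SE 0.22) and TAF5 mRNA 2.64-fold lower (-1.40, SE 0.22). The largest falls were in the sterol acyltransferase gene ARE1 (7.18-fold), BTN2 (6.81-fold), the methyltransferase gene SET5 (6.45-fold), PRP31 of the spliceosome (6.40-fold), TPK3, a protein kinase A subunit (6.14-fold), and PDR10, an ABC transporter (5.99-fold). HSP26, a small heat shock protein gene, rose 7.56-fold, DDR2 7.18-fold, EGO4 3.88-fold, RTC3 3.73-fold, ARG1 3.58-fold and HSP12 3.47-fold. Adjusted p-values of these 12 genes lay between 1.12e-08 and 3.79e-12, with n = 2 arrays per group.

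General stress genes again rose more often than they fell, 16 against 2 of 31 (14 and 2 adjusted over the list alone), with a median of 0.46 that is 1.64 above that of all genes and an adjusted p = 0.121 with an estimated correlation. All 97 ribosome biogenesis genes fell, also adjusted over the list alone, with a median of -1.40 (adjusted p = 0.956 with an estimated correlation). CBF5 fell 2.97-fold and NOP58 2.31-fold. Of 127 ribosomal protein genes 28 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.32, which is 0.86 above all genes (adjusted p = 0.649 with an estimated correlation). RPL30 fell 1.52-fold (adjusted p = 0.125 without replicate 2 without rapamycin), RPS31 (-0.46) did not pass at an adjusted p of 0.0532 (0.00309 without replicate 1 without rapamycin), and RPL13A had a change of 0.003. All 14 SAGA genes, 14 of 15 TFIID genes, 14 of 14 haploid mating genes and 12 of 12 genes of G2 and M phase fell, as many as adjusted over each list alone. SPT20 fell 3.04-fold, TRA1 2.58-fold, SPT15 2.31-fold, FUS1, of mating cell fusion, 4.11-fold, and the polo kinase gene CDC5 2.52-fold. With an estimated correlation, the adjusted p-value of each of these last 4 lists was 0.956. Of 9 histone genes 0 fell and 2 rose (0 and 1 adjusted over the list alone, adjusted p = 0.121 with an estimated correlation), while HTA1 (0.09), HTB1 (-0.21) and TDH3 (-0.03) did not pass.

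The spike-in itself differed in this comparison. Of 1397 S. pombe probe sets 762 changed, 311 lower and 451 higher, although the labels name no rapamycin for the S. pombe cells. The array medians changed by -1.20 (n = 2 per group, exact permutation p = 0.333, the smallest possible). With equal S. cerevisiae medians 788 genes were lower and 1378 higher, and the medians of ribosomal proteins (0.95), glycolysis (0.95), respiration (0.86) and histones (1.25) lay above 0, while that of TFIID genes was 0.005, with SPT15 (0.058) and NOP58 (0.061) also above 0. On the values as deposited the medians of ribosomal proteins (0.21), glycolysis (0.21), respiration (0.12) and histones (0.51) were above 0. Under a loess scaling through the spike-in, 125 of 127 ribosomal protein genes fell, with a median of -1.64 against -1.59 for all genes, so they no longer lay above it. Histones then had a median of -1.28, with 8 of 9 lower, and stress genes one of 0.064, with 11 higher and 5 lower.

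**Figure D3:**
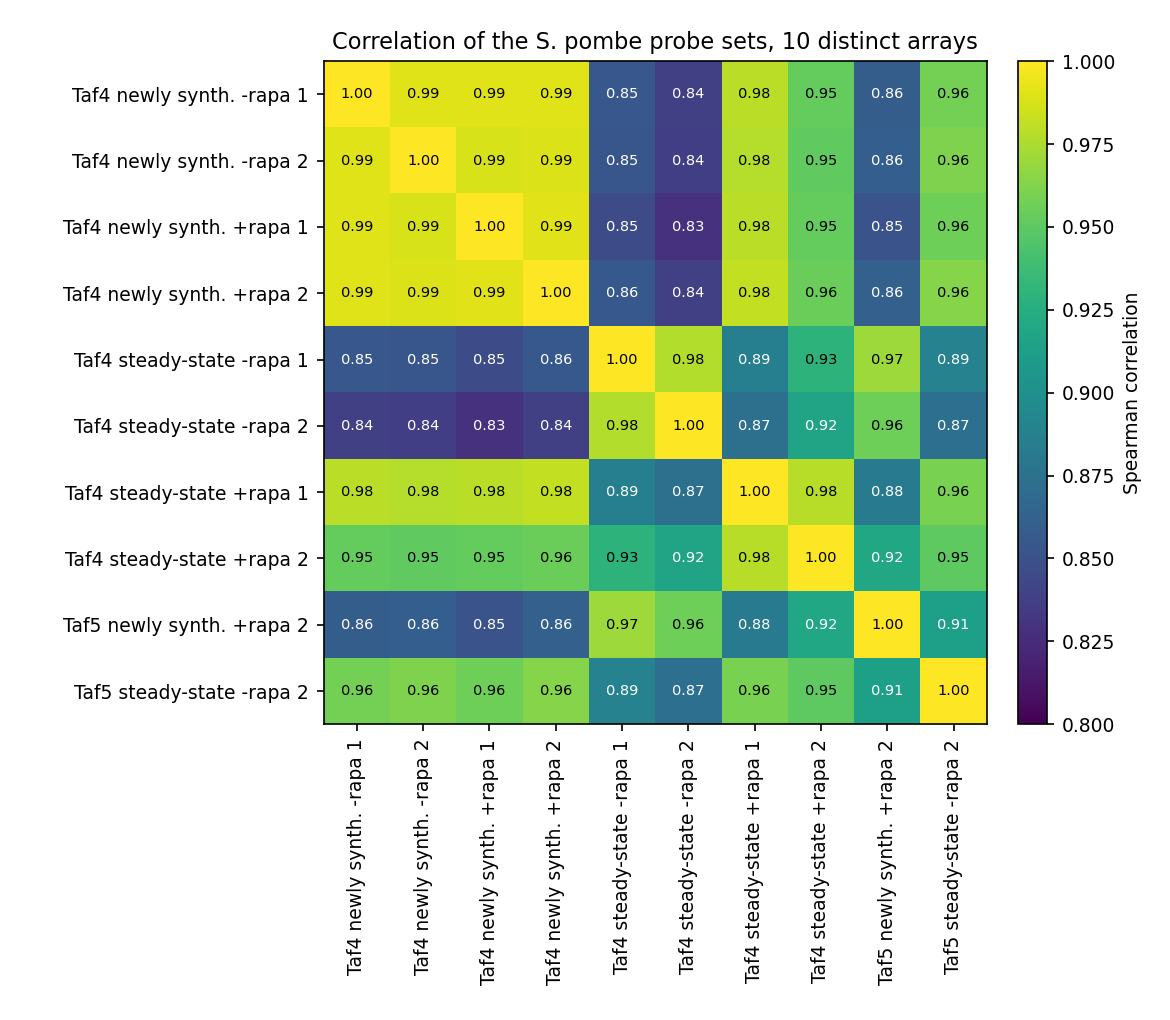
Spearman correlation of the S. pombe probe sets between the 10 distinct arrays (both axes, deposited labels, rapa for rapamycin, last digit the replicate). Both arrays labelled Taf4 steady-state without rapamycin correlate at 0.977 with each other, and Taf4 steady-state replicate 1 with rapamycin correlates at 0.886 with the first of them and at 0.979 with Taf4 newly synthesized replicate 1 without rapamycin.

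The Taf4-labelled comparisons of newly synthesized and of steady-state RNA share no arrays. They are not shown to be independent, since labelled RNA is purified from total RNA and the same cultures may feed both. Both also come from 1 fit with a common spread per gene. 3305 genes were lower in both, against 3010 for independent lists of these lengths, and 41 were higher in both, against 1.08. 3 genes that were lower in newly synthesized RNA were higher in steady-state RNA. Across genes, which are not independent replicates, the changes correlated with Pearson's r = 0.747 and Spearman's rho = 0.688.

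A test of the difference between those changes asks whether the fall differed between the fractions. With the change in steady-state RNA subtracted from that in newly synthesized RNA, 56 of 4360 genes differed by limma, 6 in the negative and 50 in the positive direction. HAC1, the transcription factor gene of the unfolded protein response (-1.38, SE 0.30, adjusted p = 0.021), and HSP26 (-1.34, SE 0.32, adjusted p = 0.0347) were among the 6. SLX5, of a SUMO-targeted ubiquitin ligase (1.70, SE 0.33), and APL5, of an adaptor complex (1.59, SE 0.33), were among the 50, each with an adjusted p of 0.021. HAC1 did not pass when any 1 of 6 of the 8 arrays was left out (adjusted p = 0.0608 to 0.274), HSP26 for 5 (0.0544 to 0.274), APL5 for 3 (0.0987 to 0.349) and SLX5 for 2 (0.0805 and 0.293). With equal S. cerevisiae medians the direction turned, with 58 genes in the negative and 19 in the positive direction, and under a loess scaling the counts were 7 and 2580. In the same test 456 of 1397 S. pombe probe sets differed. The count was 0 without Taf4 steady-state replicate 2 without rapamycin or replicate 1 with it, and 780 and 1126 without the other replicate of each; it was 2 without Taf4 newly synthesized replicate 1 without rapamycin, and 28 and 8 without replicates 1 and 2 of that fraction with rapamycin.

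In the columns labelled Taf5 newly synthesized, 3844 genes were lower and 2 higher with rapamycin, and the median gene was 2.80-fold lower (-1.49). 3 of these 4 columns are arrays that also carry the Taf4 steady-state label, so the result is not independent of that comparison. NOP19, of ribosome assembly, fell 7.58-fold (-2.92, SE 0.41) and FUS1 7.04-fold (-2.82, SE 0.41). HAC1 rose 1.83-fold (0.87, SE 0.36, adjusted p = 0.0356). AIF1, a mitochondrial cell death factor gene, was also called lower, but its signal of 1.22 (log2) in replicate 2 with rapamycin, the uncopied array, is as low as that of URA3 in the arrays labelled Taf4, so no fold is given. Without that array AIF1 was 4.30-fold lower (adjusted p = 0.303) and HAC1 did not pass (adjusted p = 0.224). Neither gene passed without replicate 1 or 2 without rapamycin, with adjusted p-values of 0.0803 and 0.109 for AIF1 and 0.13 and 0.0995 for HAC1. All 97 ribosome biogenesis genes fell, also adjusted over the list alone, with a median of -1.71, and 6 of 31 stress genes fell (1 adjusted over the list alone) while 0 rose (adjusted p = 0.781 and 0.545 with an estimated correlation). The array medians changed by -1.51 (n = 2 per group, exact permutation p = 0.333, the smallest possible). No gene passed with equal S. cerevisiae medians, 1128 passed on the values as deposited, and 0 S. pombe probe sets passed, with 165 at an unadjusted p under 0.05. That 0 does not show an even spike-in. The S. pombe changes had an SD of 0.48 here, against 0.158 under the Taf4 newly synthesized labels. Across S. pombe probe sets the 2 columns with rapamycin correlated at Spearman's rho = 0.883, against 0.991 for those labelled Taf4 newly synthesized with rapamycin.

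In the columns labelled Taf5 steady-state, 2171 genes were lower and 7 higher with rapamycin, with a median gene 1.86-fold lower (-0.89). 3 of the 4 columns are arrays that also carry the Taf4 newly synthesized label. BTN2 fell 5.32-fold (-2.41, SE 0.35), PRP31 5.44-fold (-2.44, SE 0.46) and TAF4 8.73-fold (-3.13, SE 0.92), and HSP26 rose 5.13-fold (2.36, SE 0.89) and ARG1 4.61-fold (2.21, SE 0.71). Without replicate 2 without rapamycin none of these 5 genes passed, with adjusted p-values of 0.141, 0.141, 0.278, 0.33 and 0.16, and TAF4 was 2.60-fold lower. HSP26 and ARG1 also failed to pass without replicate 1 without rapamycin (adjusted p = 0.055 and 0.107). Of 31 stress genes 5 rose and 0 fell (0 and 0 adjusted over the list alone), and of 97 ribosome biogenesis genes 68 fell and 0 rose (78 and 0 adjusted over the list alone; adjusted p = 0.544 and 0.958 with an estimated correlation). The array medians changed by -0.95 (n = 2 per group, exact permutation p = 0.333, the smallest possible). The count of 2178 genes became 0 without replicate 2 without rapamycin, the uncopied array, and 70 or 122 without replicate 1 or 2 with rapamycin; it was also 0 on the values as deposited and with equal S. cerevisiae medians.

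Tests of Taf4 against Taf5 depletion found no gene by limma at an adjusted p under 0.05 in newly synthesized RNA (1118 at an unadjusted p under 0.05) or in steady-state RNA (220). The median difference, Taf4 minus Taf5, was 0.69 and -0.26. With 1 array left out at a time it ranged from 0.526 to 0.85 and from -0.458 to -0.0672. In simulated data of this design, 80.3% of log2 differences of 2 were recovered in newly synthesized RNA and 7.46% of differences of 1, so smaller differences were mostly not detectable. In newly synthesized RNA this largely repeats the test of newly synthesized against steady-state changes under the Taf4 labels, since 3 of the 4 Taf5 columns are arrays that also carry the Taf4 steady-state label. Without the uncopied array, newly synthesized replicate 2 with rapamycin, the count was 1126, as it was in that other test without Taf4 steady-state replicate 2 with rapamycin, where the arrays left are the same ones. Without replicate 1 with rapamycin the count was 2564, and in steady-state RNA it was 143 or 55 without replicate 1 or 2 of Taf5 without rapamycin, and 1 without either replicate with it. Under a loess scaling through the spike-in it was 2660 and 444. The change in newly synthesized RNA differed from that in steady-state RNA under the Taf5 labels for 0 genes by limma, with 488 at an unadjusted p under 0.05. That count was 902 without newly synthesized replicate 1 with rapamycin and 10 or 12 without steady-state replicate 1 or 2 with it.

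Without rapamycin, the columns labelled Taf5 newly synthesized had 3270 genes higher and 38 lower than those labelled Taf4 newly synthesized. BTN2 was 6.47-fold higher (2.69, SE 0.28) and HAC1 4.34-fold lower (-2.12, SE 0.30). All 4 of these arrays also carry Taf4 labels, under which the same contrast is steady-state against newly synthesized RNA of 1 strain. Between the columns labelled steady-state, 3206 genes were lower and 51 higher under the Taf5 label. Replicate 1 of these Taf5 columns is an array that also carries the Taf4 newly synthesized label, and replicate 2 is an uncopied array. A difference of strain therefore cannot be told apart from one of RNA fraction here. S. pombe probe sets differed as well in the 2 contrasts, 603 and 786 of 1397. With equal S. cerevisiae medians the counts were 263 higher and 862 lower, and 453 lower and 1067 higher. On the values as deposited, in which the columns labelled Taf5 were scaled to a lower mean, all called genes were lower under the Taf5 label, 3992 in newly synthesized and 4349 in steady-state RNA, and BTN2 was at -0.060.

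Over both strain labels, array medians were lower with rapamycin by -1.16 in newly synthesized and by -1.08 in steady-state RNA, with n = 4 columns per treatment. Exact permutation within strain labels gave a two-sided p = 0.0556 for each, the smallest of its 36 arrangements. The 2 results share 6 arrays.

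Marker genes separated the 2 uncopied Taf5-labelled arrays from the 8 arrays labelled Taf4. URA3, a uracil synthesis gene, reached at most 3.27 (log2 signal) in the 8 arrays labelled Taf4 but 10.1 and 9.04 in Taf5 steady-state replicate 2 without rapamycin and Taf5 newly synthesized replicate 2 with it. LYS2 was at most 3.96 against 9.35 and 8.98, and LEU2 at most 5.24 against 9.83 and 9.70. AIF1 was at least 7.03 in the 8 arrays and 0.78 and 1.22 in the pair. HIS3, a histidine synthesis gene, was also lower in the pair, at 7.63 and 6.85 against at least 10.2. ADE2, an adenine synthesis gene, did not separate them, with 8.25 to 10.3 in the 8 arrays and 9.64 and 9.08 in the pair. TAF4 mRNA was at most 8.46 in the 8 arrays and 10.5 and 9.86 in the pair, whereas TAF5 mRNA was at least 7.97 against 7.59 and 7.15. The alpha-factor gene MF(ALPHA)1 was above 11 in all 10 arrays and the a-factor gene MFA1 at most 6.11, and all labels name MATalpha cells of the W303 background. The genotype label of the Taf5 samples names the FRB tag on TAF4.

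**Figure D4:**
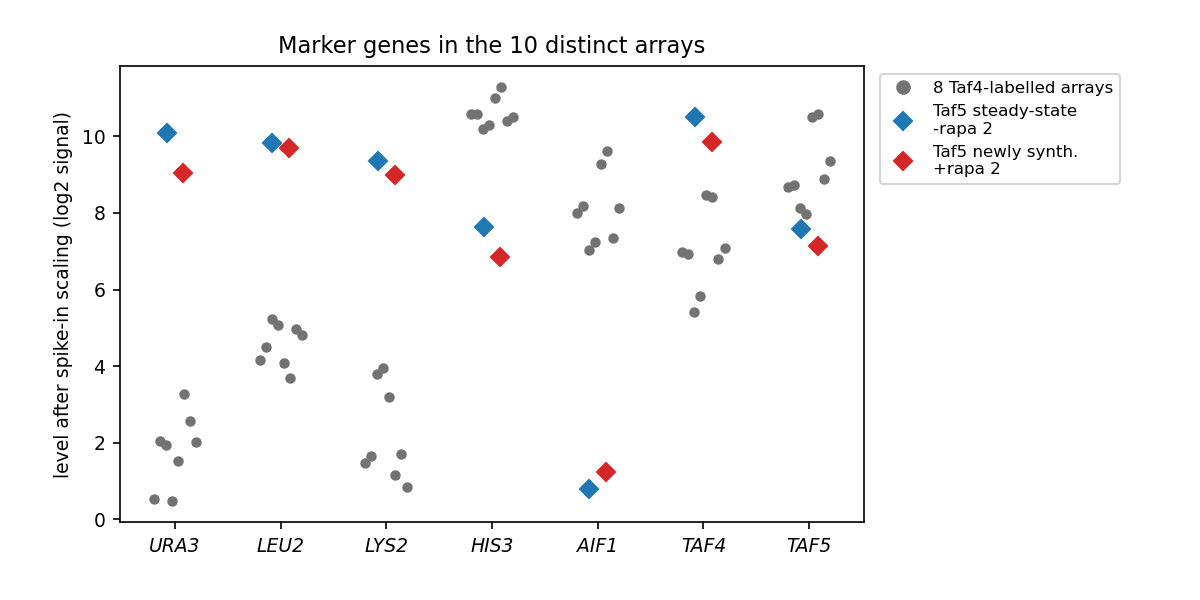
Level of 7 marker genes (x axis) after spike-in scaling (y axis, log2 signal) in the 8 arrays labelled Taf4 (grey points) and the 2 uncopied Taf5-labelled arrays (diamonds). URA3, LEU2 and LYS2 lie at 5.24 or below in the 8 arrays and at 8.98 or above in the pair, and AIF1 is reversed. HIS3 is reversed too, at 10.2 or above in the 8 arrays and at 7.63 and 6.85 in the pair.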

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

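The tests of fraction, strain background and cross-hybridisation and the comparison of S. pombe profiles in this part were chosen after the values had been seen; the test of signal-dependent scaling was chosen before its result.

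The S. pombe probe sets, a spike-in that no comparison was meant to test, differed in arrays in which they should be alike. With rapamycin, 762 of 1397 changed in the arrays labelled Taf4 steady-state, against 0 in those labelled Taf4 newly synthesized. Whether RNA of S. cerevisiae on S. pombe probe sets contributed is not settled. 0% were called in the Taf4 newly synthesized arrays, where S. cerevisiae levels fell as well. Without rapamycin, however, the S. cerevisiae median lay only 0.99 and 1.13 (log2) above that of S. pombe there. In the Taf4 steady-state arrays it lay 2.21 and 2.54 above, a level that the newly synthesized arrays do not reach. Signal-dependent scaling as the whole cause is argued against by the loess scaling, which left a count equal to 98.2% of those calls. RNA of the other fraction in the rapamycin arrays stays open: across S. pombe probe sets, the change correlated at r = 0.878 with the fraction difference without rapamycin, with separate control arrays (0.856 with the controls exchanged). With an uncopied Taf5-labelled array in their place, r was 0.170 for newly synthesized replicate 2 with rapamycin and 0.825 for steady-state replicate 2 without it. The high value is therefore not given by every array, but an array without rapamycin reaches it too, and it does not tell whether the rapamycin arrays or their controls hold RNA of the other fraction. The design gives S. pombe no treatment, so no biological explanation was tested.

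The change in newly synthesized RNA differed from that in steady-state RNA for 56 genes under the Taf4 labels, by a test of the difference itself, and 456 S. pombe probe sets differed in the same test. In the test of Taf4 against Taf5 depletion in steady-state RNA, 158 S. pombe probe sets differed.

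The second pattern is the scans that carry 2 sets of labels. Newly synthesized RNA in the arrays labelled Taf4 steady-state without rapamycin, as their copies under the Taf5 label state, may explain part of it. Ribosome biogenesis genes, whose mRNAs are short-lived, had a median difference of 1.44 (log2) over the arrays labelled Taf4 newly synthesized, at the 100th percentile of 10000 random lists matched on level, whose median was 0.96. Ribosomal protein genes, with long-lived mRNAs, lay at -0.04 against 0.43 for matched lists. Apart from the extremes, the medians of those matched lists spanned only 0.423 to 0.459. The same few bright genes may recur in most of them, so the value for ribosomal proteins carries little weight. A strain background that differs between the 2 uncopied Taf5-labelled arrays and the 8 Taf4-labelled arrays may also apply. 4 genes (URA3, LYS2, LEU2 and AIF1) lay more than 4 (log2) outside the range of the 8 in both uncopied arrays. Which of the 2 sets departs from the W303 background that all labels name was not tested. The S. pombe profiles of the 2 uncopied Taf5-labelled arrays side with the copies' Taf5 fraction labels: newly synthesized replicate 2 with rapamycin correlated across probe sets at rho = 0.971 with the array labelled Taf4 steady-state replicate 1 without rapamycin, deposited also as Taf5 newly synthesized, against 0.859 with Taf4 newly synthesized replicate 1, and steady-state replicate 2 without rapamycin at 0.889 against 0.958. The copied array labelled Taf4 steady-state and Taf5 newly synthesized replicate 1 with rapamycin goes against both of its fraction labels (0.886 against 0.979). Under either set of labels it lay nearer to the array of the other fraction. Taf4 steady-state replicate 2 with rapamycin, which has no copy, was also nearer to the array labelled Taf4 newly synthesized (0.929 against 0.953). Probe sets are not independent replicates, and these profiles compare the arrays only with one another. Which label of each copied scan is right, if either is, therefore stays open.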

How the results depend on the processing

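The 16-column fit and the shift from unchanged S. pombe probe sets were chosen after seeing the data; the cause of the shifts below was not tested unless stated. The falls under both Taf4 labels stayed the larger direction under each alternative except equal S. cerevisiae medians, which by construction removes a common fall. Counts below are genes called by limma.

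With equal S. cerevisiae medians, 1067 genes were called in Taf4 newly synthesized RNA (391 lower, 676 higher, against 3466 and 76), 2166 in Taf4 steady-state RNA (788 lower, 1378 higher, against 3792 and 62), 0 under each Taf5 label, and 1125 (862 lower) and 1520 (453 lower) between strains without rapamycin in newly synthesized and steady-state RNA. In newly synthesized RNA under Taf4 labels GUA1 (0.025), SSE1 (0.083), SPT20 (0.092), SPT15 (0.11), CDC5 (0.11), TRA1 (0.16), TAF5 (0.17), TDH3 (0.36), RPL30 (0.39), RPS31 (0.45), HTB1 (0.63) and HTA1 (0.71) then turned positive. In steady-state RNA SPT15 (0.058), NOP58 (0.061), SSE1 (0.11), SNQ2 (0.45), PDR5 (0.55), RPL30 (0.66), RPS31 (0.81), HTB1 (1.06) and TDH3 (1.24) did so.

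On the values as deposited, which keep the authors' scaling, 2310 and 1128 genes were called in newly synthesized RNA under the Taf4 and Taf5 labels, 0 in Taf5 steady-state RNA and 106 for the newly synthesized against steady-state change under Taf4. Between strains it called 3992 and 4349 genes, all lower under Taf5, since those columns were scaled to a lower mean. Array medians changed by -0.43 and -0.68 in newly synthesized and by -0.67 and -0.53 in steady-state RNA for Taf4 and Taf5, and by -0.55 and -0.60 over both. RPS31 (0.0098), HTB1 (0.18) and HTA1 (0.26) turned positive in newly synthesized and RPS31 (0.071), HTB1 (0.32) and TDH3 (0.50) in steady-state RNA under Taf4, and BTN2 between strains was -0.060.

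With equal S. cerevisiae medians the newly synthesized against steady-state change under Taf4 gave 58 genes lower and 19 higher, against 6 and 50.

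The loess curve called 2660 and 444 genes for Taf4 against Taf5 in newly synthesized and steady-state RNA and 2587 and 753 for newly synthesized against steady-state changes under Taf4 and Taf5. Medians were -0.72 and -1.88 in newly synthesized RNA and -1.58 in Taf4 steady-state RNA, and HTA1 was 0.025 in newly synthesized and -1.32 in steady-state RNA under Taf4. The upper S. pombe probe sets gave 260 genes for newly synthesized against steady-state under Taf4, and in Taf4 steady-state RNA HTA1 -0.043 and RPL13A -0.13. No filter gave 2 for that change, 1 under Taf5, and 1 for Taf4 against Taf5 in steady-state RNA. Leaving out the lowest 40% gave 1416 in Taf5 steady-state RNA, where fewer genes were tested, and a Taf4 newly synthesized median of -0.70. An intensity trend gave 210 for newly synthesized against steady-state under Taf4, and all 16 columns 0. Using the 8 arrays of the fraction gave 2344 in Taf4 newly synthesized RNA; for tests between strains it is the fit already used. Camera called 0 lists in each of the 4 contrasts with an estimated correlation. Unchanged S. pombe probe sets, 819 of 1746, moved no median by as much as the replicate spread. These probe sets were picked as unchanged after each array had been shifted to equal S. pombe medians. A similar shift therefore largely follows from the choice, and this alternative cannot tell whether the spike-in scaling is right.

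Same-numbered samples deviated together with correlations of 0.12, 0.18, 0.17 and 0.12 over 2 pairs each, and the labels do not say that a number marks portions of 1 culture or RNA of 1 extraction, so the numbers are not treated as pairs and a pairing stays open. With the replicate block, 1629 genes were called for newly synthesized against steady-state under Taf4 and 41 under Taf5; counts for the other contrasts stayed within 1.5 times, at 3952, 3840, 4040 and 1633 for Taf4 newly synthesized, Taf5 newly synthesized, Taf4 steady-state and Taf5 steady-state RNA.

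Leaving out 1 array at a time, which leaves a lone array assumed to vary like the other groups, gave 0 to 2391 genes in Taf5 steady-state RNA, 0 to 2564 and 0 to 143 for Taf4 against Taf5 in newly synthesized and steady-state RNA, and 0 to 1126 and 0 to 902 for newly synthesized against steady-state under Taf4 and Taf5. It gave 2444 to 3132 in Taf4 newly synthesized, 2731 to 4004 in Taf5 newly synthesized and 3588 to 3929 in Taf4 steady-state RNA. In steady-state RNA under Taf4, TDH3 ranged from -0.14 to 0.081, HTA1 from -0.0059 to 0.19, HTB1 from -0.46 to 0.051 and RPL13A from -0.13 to 0.14, and in newly synthesized RNA GLN1 ranged from -0.069 to 0.099. Of 1280 values of single genes over all alternatives, 1102 kept direction and side of the threshold, 119 no longer passed, 19 newly passed and 40 changed sign.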

Other observations

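In the arrays labelled Taf4 newly synthesized, further lists had medians above that of all genes (-0.78), and none passed with an estimated correlation. Among them were cell wall (-0.29), M to G1 daughter genes (-0.32), the iron regulon (-0.35), the phosphate regulon (-0.37), the proteasome (-0.45) and G1 and S phase (-0.51), whose adjusted p-values with an estimated correlation were 0.784, 0.887, 0.742, 0.887, 0.887 and 0.887; with S. cerevisiae medians made equal these 6 medians lay above 0, from 0.31 to 0.53, and on the values as deposited those of cell wall (0.089), M to G1 (0.058), iron (0.031) and phosphate (0.012) did. Of 12 drug efflux genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of 0.085, and GRE2, a stress-induced reductase gene, rose 1.61-fold (adjusted p = 0.0626 without replicate 1 without rapamycin); in Taf4 steady-state RNA 7 fell and 0 rose, with PDR5 1.65-fold and SNQ2 1.76-fold lower, and PDR5 did not pass without replicate 2 without rapamycin or replicate 1 with it (adjusted p = 0.099 and 0.0829). Of 16 genes that rise under nitrogen limitation and rapamycin-type inhibition of TORC1, 6 fell and 2 rose (4 and 2 adjusted over the list alone), and the glutamine synthetase gene GLN1 had a change of 0.01. Amino acid biosynthesis had 36 of 56 genes lower and 3 higher, with ASN1 at 0.14. With S. cerevisiae medians made equal, the medians of the nitrogen (0.63) and amino acid lists (0.27) were above 0, and on the values as deposited that of the nitrogen list (0.19). In Taf4 steady-state RNA the median of the drug efflux list turned from -0.73 to 0.54 with equal medians, with PDR5 (0.55) and SNQ2 (0.45). With an estimated correlation, the adjusted p-values of the drug efflux, nitrogen and amino acid lists were 0.706, 0.706 and 0.887.

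Mating and nucleotide genes fell with the rest in the same arrays. All 4 alpha-specific genes fell, STE3 by 2.32-fold, and 13 of 14 haploid mating genes fell, FUS1 by 2.47-fold. 22 of 23 nucleotide synthesis genes fell, GUA1 by 1.74-fold, and 9 of 12 genes of G2 and M phase, with CDC5 1.64-fold and SWI5 1.84-fold lower. 15 of 21 chaperone genes fell and 1 rose, with SSE1 1.67-fold lower. Without replicate 2 without rapamycin SSE1 and CDC5 did not pass (adjusted p = 0.0532 and 0.0585), nor did CDC5 without replicate 2 with rapamycin (0.0658). With S. cerevisiae medians made equal, the medians of the chaperones (0.14) and of G2 and M phase (0.024) were above 0, with SSE1 (0.083), CDC5 (0.11) and GUA1 (0.025). With an estimated correlation, the adjusted p-values were 0.887, 0.893, 0.887, 0.962 and 0.962.

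The third pattern is that bright genes fell less in the arrays labelled Taf4 newly synthesized: the median was -0.46 in the brightest 10% of genes and -0.89 in the dimmest 10%. Both tests below were chosen before their results were seen. If compression of bright signals alone set the small fall of the ribosomal proteins, their median (-0.46) should lie inside the range of random lists matched on level; it lay at the 0th percentile of 10000 such lists, below their median of -0.37, so neither bound set in advance was met and the test leaves compression open. In Taf4 steady-state RNA the same list lay on the other side, at the 100th percentile (-0.32 against -0.46). The matched lists were drawn from 20 level bins without the 127 ribosomal protein genes themselves. Apart from the extremes, their medians in newly synthesized RNA spanned only -0.394 to -0.36. The same few bright genes may recur in most of them, so both percentiles for this list carry little weight. Slow mRNA turnover is another candidate explanation. After removing level, the change correlated across genes at r = -0.16 with the ratio of Taf4-labelled steady-state to newly synthesized levels. With the controls exchanged r was -0.10, and the result lay between the bounds set in advance. If long-lived mRNAs fell less, r should be positive under the Taf4 fraction labels as given, and the values were negative. With the fraction labels swapped, the expected sign would be negative. Which fraction labels are right stays open, so this test cannot decide on turnover. Histone, respiration and stress genes lay above nearly all matched lists (percentile 100 for each), with medians of -0.04, -0.22 and 0.86 against -0.48, -0.67 and -0.79.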
